A study of Mus musculus with 2 samples.

How the data were processed

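RNA sequencing of 2 libraries of 32Dcl3 cells was analysed, 1 from cells infected with a scramble control virus and 1 from cells infected with a hairpin virus against Bcat1. Both were grown with 10% fetal bovine serum and 10% conditioned medium that supplies interleukin-3, per the labels' protocols. Cells were taken on day 5 and sorted by flow cytometry, and 5 ug of total RNA entered each library, per the labels' protocols. The titles and treatment fields were used to assign the groups. The description field of the hairpin library names scramble as well, which goes against its own title and treatment field.

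The authors deposited a table of whole-number read counts per gene for both libraries, with each gene's location, strand, type and a transcript length. The genome build is mm10, per the submitters' processing notes. The aligner, the counting tool, the treatment of reads that map to several places and the use of strand are not given in the sources used here. Without these, reads of a gene cannot be told apart from those of a near-identical copy, an overlapping gene or an antisense partner. The table holds 46095 rows, of which 20758 had a count in at least 1 library. It places 1724 rows on 134 sequences outside chromosomes 1 to 19, X, Y and MT. By symbol, 1571 of these rows have a place on a main chromosome in the RefSeq annotation of GRCm38.p6. Of 39897 rows on main chromosomes found in that annotation by symbol, 87.3% had the same chromosome and the same start or end.

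Total counts were 37479384 in the scramble library and 32697427 in the library labelled shBcat1. A count of 0 allows up to 3 counts where the reads of a gene could be counted, which is 0.0800 and 0.0918 CPM, counts scaled to the library total, in these libraries. Rows with at least 1 CPM in at least 1 library were analysed, 11692 in all. Counts were scaled by the trimmed mean of M values (TMM) of edgeR 4.0.16 in R 4.3.3, with factors of 0.991 and 1.01. For each gene the ratio of scaled counts, shBcat1 over scramble, was computed in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Each ratio has a 95% interval from the exact Clopper-Pearson bounds of the split of its counts between the libraries. These intervals and floors cover counting error only. Because each group has 1 library, no test between the conditions was made, no p-value is given, and no difference has a replicate check.

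Genes were counted as higher or lower where the ratio was at least 2-fold and its interval excluded 1. A set of 43 gene lists, covering metabolism, amino acid sensing, stress, signalling, cell cycle, interferon, markers of other blood and stromal cell types, and signs of RNA or sample quality, was written before the data were examined. Of their 1071 entries, 1070 matched a row by symbol. A list member was counted at 1.5-fold with an interval excluding 1. The median log2 ratio of each list with at least 5 analysed members was placed among the medians of 10000 random lists of the same size drawn from the same 10 bins of mean expression. A list was said to stand apart below percentile 2.5 or above 97.5, as a description of these libraries. Genes were named by a rule also written before the data were examined. It takes Bcat1 and Bcat2, the 15 genes per direction with the largest fold at the interval bound nearest to 1, leaving out symbols of predicted genes, clone names, pseudogenes and small RNAs, and a fixed set (Msi2, Myc, Kit, Abl1, Bcr, Creb1, Mtor and Atf4). It also takes up to 4 members, in the direction of most members, of each list that stood apart or had at least 3 members past 1.5-fold in 1 direction, and the 2 members with the highest mean of each other list. A few genes that the rule takes are not reported here. Other genes named in the text were chosen after their values were seen.

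The ratio and list procedures were tested on simulated data, with counts drawn at the depth of both libraries and 200 genes changed. Of the simulated genes 11571 passed the filter, 197 of the changed ones among them. The 2-fold rule called 49 of 49 genes simulated at 3-fold, 50 of 50 at 5-fold, 49 of 49 at 10-fold, 0 of 49 at 1.5-fold and 5 of 11374 unchanged genes. The counting intervals held the simulated fold for 95.5% of genes, and 5 of 100 unchanged lists of 25 genes fell outside percentiles 2.5 to 97.5. The simulation holds no variation between cultures.

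Alternatives were scaling by total counts, by the median-of-ratios size factors of DESeq2 1.42.0 and by the upper quartile; no low-count filter or at least 5 CPM; 1.5-fold, 3-fold or fold alone; plain gene symbols; 5 or 20 expression bins or no matching; the mean of a list; and 2-fold for list members. Added after the data were seen were rows on main chromosomes alone, counts without the interferon list, added lists on main chromosomes alone, and random lists matched also on transcript length or on GC content in 5 bins within each expression bin. GC content came from the transcripts of GENCODE release M21, and 818 of 830 analysed list genes had a value.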

Results

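Gene expression was measured by RNA sequencing in 32Dcl3 cells, a murine myeloid cell line whose parental cells depend on interleukin-3. The cells measured were labelled as carrying the BCR-ABL fusion kinase with the T315I change. BCR-ABL is the driver of chronic myeloid leukaemia, and this change in its kinase domain is known for resistance to tyrosine kinase inhibitors. The study asked what Bcat1, the cytosolic branched-chain amino acid aminotransferase, contributes to such cells. There was 1 library of cells infected with a scramble control virus and 1 of cells infected with a hairpin virus against Bcat1, both collected on day 5. The libraries held 37479384 and 32697427 counts, with 11391 and 11504 rows at 1 CPM or more. With 1 library per group, every difference below is between these libraries and has no replicate check.

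Bcat1 itself had 1 count in each library. The counting interval of its ratio ran from 0.0144 to 88.4, so neither a knockdown nor its absence was detectable. The table places the Bcat1 row on a sequence outside the main chromosomes, whereas RefSeq for GRCm38.p6 places the gene on chromosome 6 from 144993835 to 145076157. Of 88 rows on that sequence, 19 passed the 1 CPM filter, among them Lrmp with 6528 and 4808 counts. Bcat2, the mitochondrial branched-chain aminotransferase on chromosome 7, was at 70.8 CPM in the scramble library and 68.8 CPM in the library labelled shBcat1, a ratio of 0.971 (95% counting interval 0.918 to 1.03). Since the targeted gene could not check the labels, each direction below refers to the library labelled shBcat1.

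Genes induced by interferon were higher in the library labelled shBcat1. Of 25 measured genes of the interferon response list, all 25 had a ratio above 1, 23 were past 1.5-fold and 18 past 2-fold. The median log2 ratio was 1.95, against a central 95% of -0.11 to 0.13 in random lists, and none of the 10000 random lists reached it. Isg15, a ubiquitin-like protein attached to other proteins in the interferon response, was at 4.60 CPM in the scramble library and 47.1 CPM in the library labelled shBcat1, 10.2-fold higher (8.74 to 12.1). Mx2, an antiviral GTPase, was 14.6-fold higher (10.2 to 21.8), and Oasl2, of the oligoadenylate synthetase family, was 9.19-fold higher (8.14 to 10.4). Ifi44 had 1 count in the scramble library and 129 in the other, a ratio of 145 with an interval of 25.6 to 5784. Irf7, a transcription factor that drives interferon genes, was at 25.5 and 128 CPM, 5.02-fold higher (4.68 to 5.39). Stat2 and Irf9, which carry the type I interferon signal to the nucleus, differed by less, with ratios of 1.92 and 1.82. Ifit2 at 1.27 and Ifi35 at 1.45 did not pass 1.5-fold. Of the 5 genes under the filter, Rsad2 had 1 and 29 counts, Ifit3 had 9 and 20, Gbp2 had 23 and 8, and Ifih1 and Cmpk2 are listed at 0, which sets no limit on their expression, as the counting rules are not given in the sources used here. The interferon genes themselves, 21 in the table, had 1 count in sum in the scramble library and 2 in the other. Summed counts of 13 monocyte and macrophage markers under 1 CPM in the scramble library, with a median of 2 there, were 89 and 64. Of 11 markers of these cells that passed the filter, 7 lay above 0 and 4 below, with 2 higher and 0 lower past 1.5-fold. A quality list of immediate early and dissociation genes was also higher, with a median log2 ratio of 0.29. The Oas, Ifit, Gbp, Mx and Trim30 families hold close copies, so the split of reads among their members is uncertain.

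**Figure D1:**
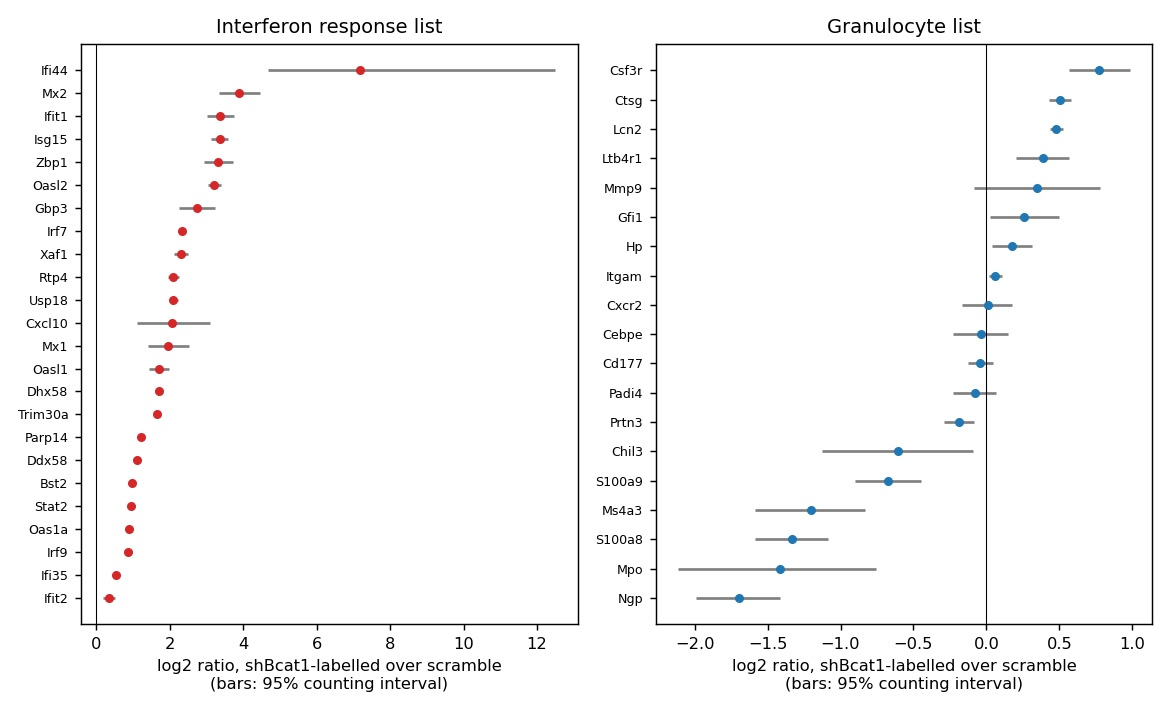
Log2 ratio of the analysed members of the interferon response list (left, 1 member not drawn) and the granulocyte list (right), library labelled shBcat1 over scramble, with 95% counting intervals as bars, 1 library per group. Every interferon response gene drawn lies above 0, whereas 9 granulocyte genes lie above and 10 below.

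Across the 11692 analysed rows, 210 were higher and 76 lower by at least 2-fold with an interval excluding 1, which is 2.45% of them. Protein-coding genes made up 143 of the higher and 51 of the lower rows. The middle of the distribution was narrow, with a median log2 ratio of 0.0016 and a 5th to 95th percentile range of -0.45 to 0.61. Of the 15 named genes furthest upward by the bound of the interval nearest to 1, 8 belong to the interferon response list, namely Ifi44, Mx2, Isg15, Oasl2, Ifit1, Zbp1, Gbp3 and Irf7. Ifit1 was 10.3-fold higher, Zbp1, a sensor of Z-form nucleic acid, 9.92-fold and Gbp3, a guanylate-binding protein, 6.65-fold. The other upward genes on main chromosomes were D17Wsu92e (8.72-fold, from 80 counts to 619), Apol9b (7.95-fold, 106 to 748) and the immunity-related GTPase Iigp1 (9.93-fold, 16 to 141). Further ones were Ifi202b (21.4-fold, from 2 counts to 38) and Atp6v1e1, a subunit of the vacuolar proton pump (6.95-fold, 35 to 216). Each of these was low in the scramble library. Apol9b and Ifi202b have close paralogs. With at least 5 CPM required, 71 genes were higher and 16 lower, and without a filter 607 and 381.

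**Figure D2:**
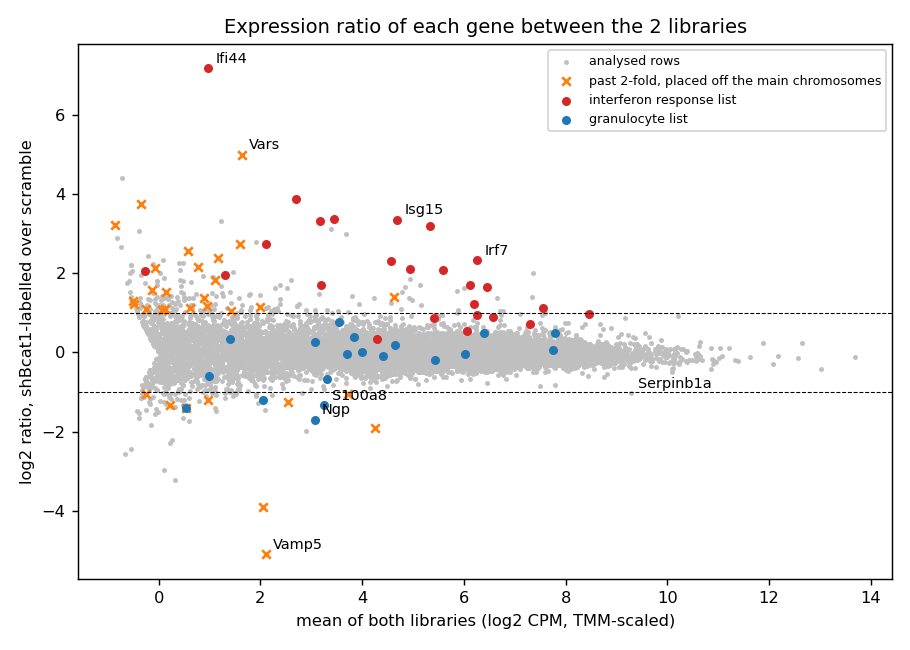
Log2 ratio of each analysed row against its mean level in both libraries (log2 CPM), with dashed lines at 2-fold. The interferon response genes (red) lie above 0 across the range of expression, Serpinb1a lies near the lower line at high expression, and 31 rows past 2-fold are placed off the main chromosomes (orange crosses).

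In the other direction, Serpinb1a, an inhibitor of neutrophil serine proteases, stood out by its level, at 839 CPM in the scramble library and 412 CPM in the library labelled shBcat1, a ratio of 0.491 (0.481 to 0.501). The Serpinb1 genes are close paralogs. Ngp, a neutrophil granule protein, was at 12.8 and 3.94 CPM, a ratio of 0.308 (0.252 to 0.375). S100a8, a calcium-binding protein of neutrophils, was at 13.7 and 5.43 CPM, a ratio of 0.397 (0.333 to 0.472). The kinase Srpk1, which acts on splicing factors, had a ratio of 0.363 (233 and 75 counts). Tnfrsf18, a receptor of the tumour necrosis factor family, was at 0.360 (119 and 38 counts). Lower counts lay behind Sprr2a3 (84 and 8 counts), Sprr2a1 (71 and 8), Igsf9b (72 and 13), Il17re (73 and 14), Mill2 (40 and 6) and the transcriptional coactivator Wwtr1 (43 and 7). Sprr2a1 and Sprr2a3 are near-identical neighbours, and their values cannot be read as independent.

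The granulocyte list held both directions. Of its 19 measured genes, 6 were lower past 1.5-fold and 1 higher, while the median log2 ratio was -0.039, at percentile 20.4 of random lists. Besides Ngp and S100a8, the lower genes were Ms4a3 (ratio 0.435, 0.333 to 0.563), S100a9 (0.626), Chil3 (0.658) and Mpo, the myeloperoxidase of primary granules (0.375, 0.231 to 0.592), whose row lies off the main chromosomes. The higher gene was Csf3r, the receptor of granulocyte colony-stimulating factor (1.71, 1.48 to 1.98). Camp, Fcnb and Mmp8 had at most 2 counts in either library. With the mean in place of the median, the list stood at -0.23 and percentile 0.18.

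Named genes placed off the main chromosomes need separate reading, since 11.0% of 281 such rows were past 2-fold (Wilson 95% interval 7.88% to 15.2%), against 2.23% of 11411 rows on main chromosomes (1.98% to 2.52%). Upward, these were Vars, the valyl-tRNA synthetase, with 7 and 198 counts, Shpk, with 4 and 48, and the lysosomal sialidase Neu1, with 36 and 69. Also upward were H2-M3 (65 and 120 counts) and Tapbp (20 and 38), both of antigen presentation. Downward, the named genes were Vamp5 (311 and 8 counts), Ncbp3 (288 and 17) and Gstp1, a glutathione transferase (1113 and 263). Slc25a11, the mitochondrial oxoglutarate carrier (306 and 113), and Mpo (78 and 26) were lower as well.

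Among lists of metabolism and amino acid supply, 3 stood apart upward. Targets of ATF4, the transcription factor of the integrated stress response, had a median log2 ratio of 0.20 over 21 genes, at percentile 99.99, with 19 above 0 and 5 higher past 1.5-fold. These 5 were Nupr1 (3.12-fold, 2.48 to 3.94), the cystine transporter Slc7a11 (1.90), the pseudokinase Trib3 (1.87), the proline synthesis enzyme Pycr1 (1.77) and Ddit3 (1.57). Atf4 itself was at 249 and 339 CPM, 1.36-fold higher (1.32 to 1.40). The 20 aminoacyl-tRNA synthetases had a median of 0.16, above every random list, with 16 above 0. Vars, off the main chromosomes, was the 1 member past 1.5-fold, and Cars (1.39), Lars (1.20) and Sars (1.18) differed by less. Genes of cholesterol synthesis had a median of 0.33, also above every random list, with 19 of 22 above 0. Insig1, which retains the sterol regulator SREBP in the endoplasmic reticulum, passed 1.5-fold at 1.69 (1.57 to 1.81), and Msmo1 (1.49) and Hmgcs1 (1.47) lay just below.

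Branched-chain amino acid catabolism, the pathway of the targeted enzyme, had a median of 0.093 over 22 genes, at percentile 96.1, inside the random range. Aldh6a1, the methylmalonate semialdehyde dehydrogenase, was the 1 member past 1.5-fold (1.70), and the highest expressed were Dld (1.20) and Acat1 (1.01). Genes of mTORC1 and amino acid sensing had a median of -0.026 (percentile 34.4), with Mtor at 0.898, in a row off the main chromosomes, Rptor at 0.943, Eif4ebp2 at 0.739 and Gatsl3 past 1.5-fold at 2.60. Amino acid transporters had a median of -0.079 (percentile 13.7), with Slc7a1 at 1.02, Slc7a5 at 0.975 and 2 members higher, Slc7a11 and Slc1a4 (1.56). The alpha-ketoglutarate-dependent dioxygenases had a median of -0.040 (percentile 30.4), with Egln3 at 0.849, Kdm5c at 0.950, and Kdm5a (1.63) and Kdm7a (1.51) past 1.5-fold. Glutamate, glutamine and tricarboxylic acid cycle genes had a median of -0.033 (percentile 47.6), with Ogdh at 0.903, Mdh2 at 0.899 and Gpt2 past 1.5-fold at 1.56.

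Of the lists of metabolism and growth, 4 lay slightly lower in the library labelled shBcat1, with no member lower past 1.5-fold in any of them. MYC targets and ribosome biogenesis genes had a median of -0.17 over 33 genes, at percentile 0.01, with 26 below 0, among them Rrp12 (ratio 0.706), the transferrin receptor Tfrc (0.754), Nop2 (0.755) and Cad, which starts pyrimidine synthesis (0.769). Glycolysis genes had a median of -0.16 (percentile 0.41) with 15 of 20 below 0, including Pfkl (0.722), Pkm (0.856), Ldha (0.865) and Eno1 (0.836), the last in a row off the main chromosomes. Nuclear genes of oxidative phosphorylation had a median of -0.12 (percentile 0.04) with 49 of 67 below 0, including Uqcr10 (0.762), Uqcr11 (0.766), Ndufb2 (0.761) and Cox4i1 (0.805). Cytosolic ribosomal proteins, which have many pseudogene copies, had a median of -0.085 (percentile 2.14) with 48 of 73 below 0, including Rps21 (0.783), Rplp0 (0.813) and Rplp2 (0.813), while Rpl24 was 1.62-fold higher. When random lists were matched also on transcript length, the percentiles were 9.81 for oxidative phosphorylation and 61.0 for ribosomal proteins. With matching on GC content they were 6.41 for glycolysis and 23.5 for ribosomal proteins. Matched random lists could draw a list's own genes, so these percentiles cannot tell length or GC content from a shift of the genes. The ribosomal list also left the outer range with at least 5 CPM (percentile 2.70), with 20 expression bins (3.20) and with the mean (6.03).

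**Figure D3:**
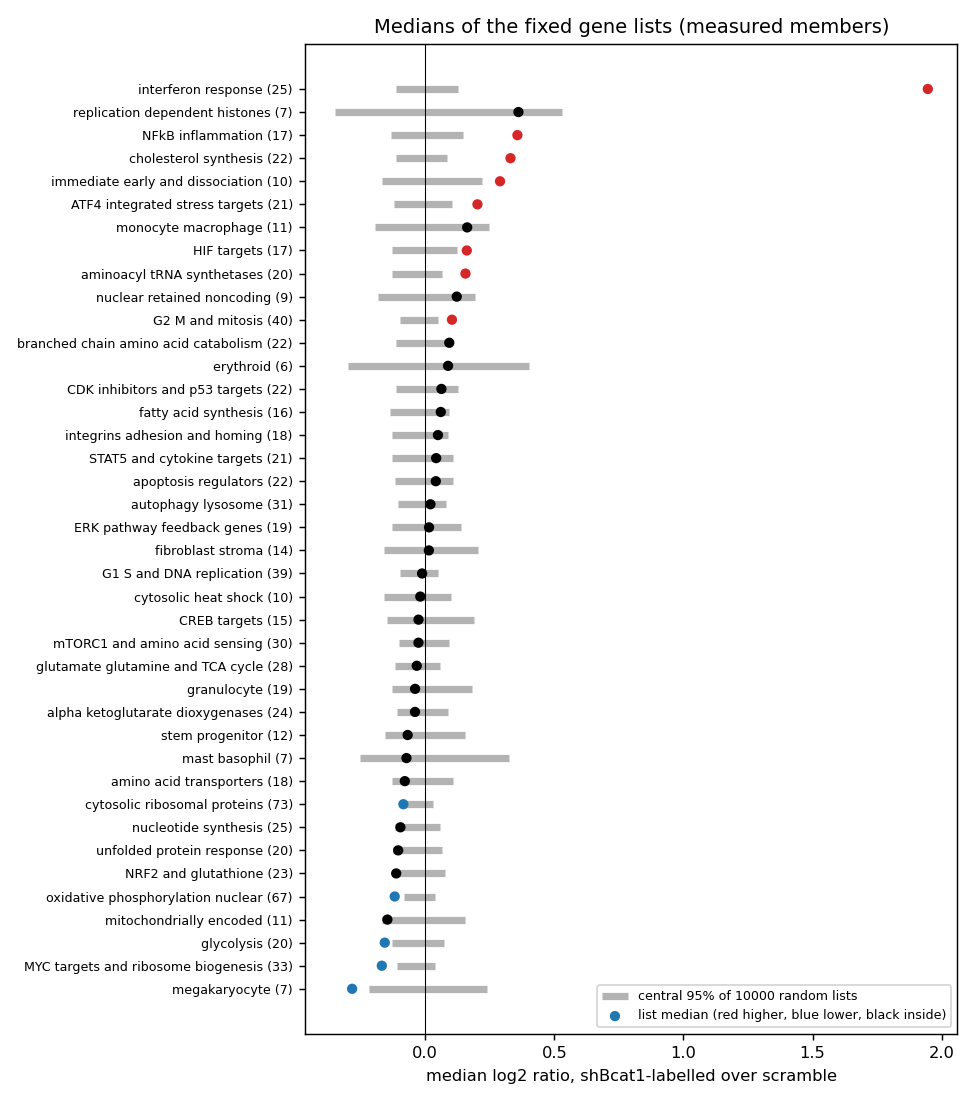
Median log2 ratio of each list with at least 5 measured genes (number in parentheses), library labelled shBcat1 over scramble, against the central 95% of 10000 expression-matched random lists (grey bars). The interferon response list lies at 1.95, whereas the medians of the other 39 lists lie between -0.28 and 0.36.

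Of the signalling and proliferation lists, 3 stood apart upward. NF-kB and inflammation genes had a median of 0.36 over 17 genes, above every random list. The chemokine Ccl3 (1.59), the NF-kB regulator Nfkbiz (1.56) and the interleukin-1 receptor antagonist Il1rn (1.72) were higher past 1.5-fold, Nfkbia was at 1.42, and Il1a was lower (0.656). G2 and mitosis genes had a median of 0.10 (percentile 99.98) with 29 of 40 above 0, including the spindle protein Nusap1 (1.56), Cenpf (1.41), the checkpoint kinase Bub1 (1.37) and Mki67 (1.31). HIF targets had a median of 0.16 (percentile 99.3), with Vegfa, the vascular growth factor, higher (1.63) and Ankrd37 lower (0.357, from 41 and 13 counts). Ero1l (1.37), Bhlhe40 (1.36) and Bnip3 (1.30) were short of 1.5-fold. With the mean in place of the median the HIF list was at percentile 74.7. A list of immediate early genes that also respond to cell handling and dissociation, fixed as a sign of sample quality, moved in the same direction as the interferon and NF-kB lists in these sorted cells. Its median was 0.29 over 10 genes (percentile 99.5), with Egr1 at 1.77, Junb at 1.44, Zfp36 at 1.35 and Ier3, off the main chromosomes, at 1.30. Its percentile was 96.2 with the mean, 96.6 without the low-count filter and 95.8 on main chromosomes alone. Of 40 lists with 5 or more measured genes, 13 stood apart, where about 2 of 40 random lists would, although some of the lists share genes. Random lists draw genes without regard to function, whereas genes of 1 list can move together between any 2 cultures. The number that stood apart is therefore no test of the conditions.

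The remaining process lists stayed inside the range of random lists. STAT5 and cytokine targets had a median of 0.042 (percentile 82.8), with Pim1 at 1.30 and Cish at 1.01, and Pim2 (1.66) and Il2ra (1.54) past 1.5-fold. ERK feedback genes were at 0.015 (percentile 57.4), with Myc at 0.946, Dusp4 at 0.976, and Egr1 (1.77) and Egr2 (1.88) past 1.5-fold. CREB targets were at -0.026 (percentile 31.4), with Gem at 1.05, Ccna2 at 0.923, and Ppargc1a past 1.5-fold at 3.38, from 11 and 33 counts. Genes of G1, S phase and DNA replication were at -0.012 (percentile 64.2), with Mcm7 at 0.962 and Mcm6 at 1.00. Nucleotide synthesis was at -0.096 (percentile 8.80), with Cad again and Rrm1 at 1.08. CDK inhibitors and p53 targets were at 0.063 (percentile 84.0), with Ccng1 at 0.866, Trp53 at 0.831 and Gadd45a past 1.5-fold at 2.78. Apoptosis regulators were at 0.041 (percentile 81.8), with Bcl2 at 1.07 and Mcl1 at 0.959. Fatty acid synthesis was at 0.060 (percentile 92.7), with Fasn at 0.849 and Scd2 at 1.15. The unfolded protein response was at -0.10 (percentile 6.90), with Hspa5 at 0.765 and Calr at 0.876.

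NRF2 and glutathione genes were at -0.11 (percentile 3.75), with Fth1 at 0.925, Ftl1 at 0.894 and Slc7a11 past 1.5-fold, and cytosolic heat shock genes at -0.019 (percentile 58.8), with Hsp90ab1 at 0.944 and Hsp90aa1 at 1.05. Autophagy and lysosome genes were at 0.020 (percentile 75.8), with Lamp1 at 0.795 and Grn at 1.11. Past 1.5-fold were Ctsl (2.08, from 26 and 48 counts) and, off the main chromosomes, Neu1 (2.16). The list of adhesion and homing genes was at 0.049 (percentile 90.0), with Cd47 at 0.970 and Pecam1 at 1.08. Mitochondrially encoded genes were at -0.15 (percentile 4.51), although the most abundant, COX1 (1.17) and ND5 (1.08), were above 1. Their share of all counts was 1.307% (Wilson 95% interval 1.303% to 1.310%) in the scramble library and 1.379% (1.375% to 1.383%) in the other. Nuclear-retained RNAs were at 0.12 (percentile 90.6), with Malat1 at 1.29, Neat1 at 1.48 and Xist, with 20 and 34 counts, past 1.5-fold. Replication-dependent histones were at 0.36 (percentile 89.5) over 7 genes, with Hist1h4i at 0.892, and Hist1h1c (1.67) and Hist1h1d (9 and 37 counts) past 1.5-fold.

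Among markers of cell types, megakaryocyte genes stood apart, with a median of -0.28 over 7 genes (percentile 0.47) and 6 of them below 0. Selp, the adhesion molecule P-selectin, had a ratio of 0.475 (0.372 to 0.603) and the integrin Itgb3 0.664 (0.647 to 0.681), whereas Fli1 (0.822) and Nfe2 (0.852) did not pass 1.5-fold. Monocyte and macrophage genes were at 0.16 over 11 genes (percentile 90.3), with Adgre1 at 1.12, Spi1 at 0.859, and Mpeg1 (2.05) and Ctss (1.84) past 1.5-fold. Stem and progenitor genes were at -0.068 (percentile 20.9), with Mecom at 1.32 and Gata2 at 0.939, and mast cell and basophil genes at -0.073 (percentile 28.5), with Slc18a2 at 0.856. Erythroid genes were at 0.088 (percentile 62.0), with Tfrc and Rhd (1.02). Fibroblast and stroma genes were at 0.014 (percentile 48.9), with 14 of 16 measured. Among them, Col1a1 was at 163.5 and 165.4 CPM (1.01) and Vim at 121.9 and 163.0 CPM (1.34). No eosinophil or B lymphoid marker reached 1 CPM, and of T and NK cell markers Gzmb (0.835) and Nkg7 (1.67) did.

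Of the genes fixed by name, Atf4 and Mtor are given with their lists. Msi2, an RNA-binding protein of blood stem cells, was at 51.2 and 60.0 CPM (ratio 1.17, 1.10 to 1.25), in a row off the main chromosomes. Myc was at 346 and 328 CPM (0.946, 0.922 to 0.970) and Creb1 at 73.6 and 79.2 CPM (1.08, 1.02 to 1.14). Abl1 (0.946, 0.906 to 0.988) and Bcr (1.17, 1.06 to 1.28) have reads that can come from the endogenous mouse genes or from the fusion, which the counts do not separate. Kit is listed at 0 in both libraries. Gapdh, a glycolytic enzyme that most cells express strongly and that has many pseudogene copies, is listed with 772 and 556 counts, so a low or missing count in this table sets no limit on expression.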

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

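The alternatives with rows on main chromosomes alone, without the interferon list, and with length or GC matching were chosen after the data were seen. The counts of 210 genes higher and 76 lower moved most with the low-count filter and the size asked for. They were 607 and 381 without a filter, 71 and 16 with at least 5 CPM, 586 and 288 at 1.5-fold, 69 and 15 at 3-fold, and 133 and 47 over plain gene symbols. Here the construction of the alternative, which admits or removes rows or changes the fold asked for, shows the cause. They were 224 and 71 with total-count scaling, 218 and 75 with upper-quartile scaling, 188 and 67 on main chromosomes alone, and 210 and 76 with median-of-ratios scaling or with fold alone. All 210 higher genes were shared with each of the 3 scalings. List members past the threshold numbered 70 at 1.5-fold and 33 at 2-fold, again by construction. Members of the interferon response list higher ranged from 18 at 2-fold to 25 without a filter, and 13 lists stood apart against 12 to 14 under the alternatives. Under the 3 scalings, 21 values of the 137 named genes left their counting interval, 390 stayed inside and none turned its sign. The scalings moved the median of all genes by at most 0.025 (log2), so for a gene past 2-fold the sign was fixed in advance. Without the interferon list, 192 genes were higher and 76 lower. The 192 still held genes of the Oas and Gbp families outside the list, such as Oas3 (4.05-fold) and Gbp7 (2.95-fold). They are therefore no count of genes apart from the interferon pattern. Over the fixed lists and all alternatives, a call ended in 11 cases, each given in the report, and arose in 7. Those that arose were granulocyte (percentile 0.18) and unfolded protein response (2.36) with the mean, amino acid transporters (2.12) and mitochondrially encoded genes (2.04) without a filter, branched-chain amino acid catabolism (98.0) with length matching, STAT5 targets (99.4) with GC matching, and histones (99.4) without expression matching. The cause of these was not tested. The authors' normalized values were not run, since the table as used here holds counts alone, and leaving out a replicate was not run, since each group has 1 library. No paired analysis was possible because each group has 1 library and no test between groups was made. Depth limits genes near 1 CPM, about 37.5 and 32.7 counts, and Bcat1 could not be assessed at 1 count.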

Other observations

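The tests of the hairpin and of shared reads, the added lists on main chromosomes alone, and the matching on length and GC content, were chosen after their patterns were seen, as were the lists and genes named here beyond the report. Antigen presentation genes of MHC class I had a median log2 ratio of 0.37 over 13 measured genes, 12 of them above 0 and 5 past 1.5-fold, at percentile 99.99 of random lists. Of these 5, all but Psme2 are in rows off the main chromosomes, and the 7 members on main chromosomes had a median of 0.25, at percentile 99.5, with 1 past 1.5-fold. H2-T22 was at 92.6 and 182 CPM (ratio 1.96, 1.88 to 2.05) and H2-M3 was 2.08-fold higher, both in rows off the main chromosomes. So were Tap1, with 24 and 42 counts (1.97, 1.17 to 3.40), and Tapbp, with 20 and 38 (2.14, 1.21 to 3.88). On main chromosomes, Psme2, an activator of the proteasome, was at 52.6 and 79.2 CPM and B2m, the light chain of class I, was 1.29-fold higher, while Psmb10 was at 0.825. The classical genes H2-K1 and H2-D1, also placed off the main chromosomes, had at most 2 counts in either library, so their level is open. A list of interferon-gamma and MHC class II genes had 5 measured members and a median of 0.26, at percentile 96.2. Nucleic acid sensors and their adaptors had a median of 0.13 over 15 genes (percentile 97.9, and 97.48, inside the range of random lists, against rows on main chromosomes alone), with the double-stranded RNA kinase Eif2ak2 (1.93) and the kinase Ikbke (1.68) past 1.5-fold, and Irf3 (0.890), Tmem173 (0.838) and Myd88 (0.796) below 1. Interferons and their receptors had 4 measured members, all receptors, with a median of 0.13, among them Ifnar1 (1.06) and Ifnar2 (0.944).

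Some further genes past 2-fold on main chromosomes were picked because they were higher, so they say nothing of how other genes of their kind behaved. Oas3 was at 64.9 and 263 CPM (4.05-fold, 3.88 to 4.24), Isg20, an exonuclease, at 13.3 and 48.1 CPM (3.61-fold), Slfn5 3.10-fold, Gbp7 2.95-fold, Ifi27l2a 2.87-fold and Oas2 2.62-fold higher. Secreted factors past 2-fold included the cytokine Lif (2.33-fold, 1.91 to 2.85) and ceruloplasmin, Cp (2.05-fold, 1.95 to 2.15).

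The pattern that most asks for follow-up is the interferon response in the library labelled shBcat1, whose 25 measured members all lie on main chromosomes. Admixed monocytes or macrophages stay open, since 13 of their markers under 1 CPM in the scramble library, with summed counts of 89 and 64 and a ratio of 0.810 (0.578 to 1.13) against a median interferon fold of 3.85, had a median of 2 counts there, too near the floor to decide. Better-counted markers went both ways, with Mpeg1 at 2.05, Ctss at 1.84, Lyz2 at 1.05 and Apoe at 0.686, and the sorting gate is not given. Transcription of interferon by the cells stays open, with 1 and 2 counts over 21 interferon genes in a table where a low count sets no limit. Infection is shared by both libraries, but a response to this hairpin or to a difference in virus dose rather than to loss of Bcat1 cannot be told apart from an effect of the knockdown, as there is 1 library with a hairpin against Bcat1, Bcat1 was not measurable, and double-stranded RNA from hairpins is a known trigger of this response.

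Rows off the main chromosomes were over-represented among genes past 2-fold, with 11.0% of them called. Low counts alone are argued against, as count-matched sets of rows on chromosomes gave a median of 13 calls (central 95% 7 to 20, highest 27) against 31 observed. Reads shared between copies of a gene on a chromosome and on another sequence may account for the pattern, which is consistent with 66.8% of protein-coding rows there having 10 or fewer counts in each library, against 48.1% on chromosomes. Vars, Vamp5, Ncbp3 and Gstp1 are among the called rows, and the Bcat1 row, which was not analysed at 1 count, is also off the chromosomes. Realigning the reads would be needed to settle it, and a biological explanation was not tested.

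Some lists shifted slightly to lower values, while others of like size, such as G2 and mitosis genes, did not. Nuclear oxidative phosphorylation genes stood at percentile 9.81 with length-matched random lists, while GC matching left them at 0.25. The central 95% of the length-matched lists was itself shifted to -0.14 to -0.028, around an unchanged list median of -0.12. Those lists could draw the list's own genes and others of like length and expression. Length matching therefore cannot tell a length trend from a shift of these genes, and gene length stays open as a source. For MYC targets and ribosome biogenesis genes, length matching gave percentile 0.07 and GC matching 0.02, which argues against either trend as the whole cause. Myc itself was at 0.946, and without replicates a difference between the cultures cannot be excluded.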
